A study of Mus musculus with 12 samples.

How the data were processed

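The series asks how well alternative splicing is detected when the amount and origin of the reads of a changed isoform are known. RNA came from D1, a mouse cell line. The labels describe 12 samples made by mixing sequencing reads on a computer. Each has a background of reads from an Illumina TruSeq library, a poly(A)-selected RNA sequencing library, made from 1000 ng or 100 ng of total RNA. To this background were added reads of listed transcripts, taken from 20M, 40M or 80M reads (M, 1e6) of a NuGENv2 library made from 2 ng of RNA or of a TruSeq library made from 100 ng. Per the labels, each background also received synthetic reads with uniform coverage, in a list with a complex background of isoforms and a list with the endogenous background. The 12 samples are therefore 2 backgrounds by 2 kits by 3 depths, and each holds 5 replicates.

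The authors deposited 6 tables, 1 for each kit and depth, with 5 columns of the 1000 ng background and 5 of the 100 ng background. Tables of the NuGENv2 kit were recognised from their names and from column names that lack the TruSeq mark. Each table had 1744 rows, of which 818 repeated another row with identical values. The remaining 926 rows were exon bins, the non-overlapping exon parts of a gene model, of 58 gene models. A bin with values that were not finite, read here as zero length, was left out, which left 925. STAR, Cuffdiff and the mm9 mouse genome are named in the submitters' processing notes, with no version. How reads were counted over bins is not given in the sources used here.

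The deposited values were a coverage signal and not FPKM (reads per kilobase and per 1e6 reads), although the tables are named so. In 9 of the 10 columns of every table the deposited signal was whole reads divided by the bin length, with no division by library size. The fifth column of the 100 ng background was divided further by a number read here as its library total in units of 1e6 reads. That number was 16 in the NuGENv2 table at 20M reads and 200.9 in the TruSeq table at 20M reads. Bin lengths and this divisor were not given and were inferred from the values themselves. Each length was the smallest that made the 9 columns whole, refined with the fifth column for 1 bin. The divisor was fitted by assuming that the fifth column gained the same reads as the first. Multiplying by bin length and, for that column, by the library total gave whole reads for 100.0% of values, within a tolerance of 0.001 reads. For the 9 columns this follows from how the lengths were found, so it checks little beyond the fifth column. Reads in bins per replicate ranged from 347941 to 593002 in the 1000 ng background and from 237258 to 492142 in the 100 ng background, leaving out the TruSeq table at 20M reads, where the latter reached 1281559. A bin with few reads is measured less precisely than one with many.

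The tests had been planned for FPKM of transcripts as deposited. Because of the units found, a different scale was used for the main results. Column size factors were the median of ratios over bins with reads in all 10 columns. The inferred library total of the fifth 100 ng column set the level of the others, so that values are FPKM equivalents. The number of calls depends strongly on this step, and the values as deposited were kept as an alternative. In the TruSeq table with 80M reads, 197 bins were called on the scaled values and 4 on the values as deposited. The latter gave 118 when the fifth 100 ng column, in another unit, was left out. The transcript of a listed spike-in could not be tested alone, because the rows are exon bins shared by isoforms.

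Each table was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off) on log2(FPKM equivalent + 1), 5 columns against 5, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low values. Bins of models with a listed transcript were always tested, and others needed a mean of at least 1. Sums over all bins of a gene model were fitted in the same way. Differences in bin usage within a model were tested with limma diffSplice. A listed transcript was counted as recovered when its gene model had at least 1 bin past the threshold with the higher mean in the background that lists it. This rule is lenient, since any bin of the model counts, so calls in the direction with no listed transcript are given beside it. Of 80 listed transcripts 78 were in the tables, and 77 had a direction, because uc009eup.1 is listed for both backgrounds.

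Kits and depths were compared by the signed log2 fold change of gene model totals, positive when higher in the background that lists the model. The 17 models listed for reads of a kit in 1 background only entered, with a sign-flip permutation over models, exact for up to 16 models and with 100000 resamples otherwise. Models are not independent replicates. Lists were compared by permutation over models. Bins that gained reads from 40M to 80M in either kit stood for the spiked isoform, and bins that gained none for the rest of the model. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Positions are from GENCODE vM1 on NCBIM37, the assembly that mm9 names, by gene symbol for 56 models and by bin length and order for 576 of 907 bins. Inferred lengths were matched to end minus start, which leaves out 1 base of each bin.

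The rule for named genes was fixed before the data were examined. It took, per list and background, the 3 models with the largest and the 2 with the smallest signed change at 80M TruSeq reads, those past the threshold in the wrong direction, unlisted models past the threshold, the model listed for both backgrounds, and the 3 that differed most between kits. It was applied to gene models, and 2 of those it took are not reported here. None of the members of the 12 gene lists fixed in advance was among the models, so gene groups could not be tested. The limma step was tested on simulated values of the 922 bins of the TruSeq table at 80M reads, with 200 bins changed. It recovered 28% of bins changed by 0.5 on the log2 scale, 70% of those changed by 1, 94% at 2 and 100% at 4, and called 0.28% of unchanged bins.

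Alternatives were other pseudocounts, filters, scalings, the eBayes trend, a minimum fold change, a replicate block, an exact permutation per bin, and leaving out each replicate. Nothing says that the replicates came from separate cultures, so p-values measure the spread between these columns only. All tables share the same background columns, and the added kit reads were the same in all 5 replicates, so tables are not independent of one another. The spread of scaled kit-read models therefore does not measure variation in the added reads.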

Results

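The data were read counts over 925 exon bins of 58 mouse gene models in D1 cells, in 12 samples. Each sample joined a TruSeq background from 1000 ng or 100 ng of RNA with reads of listed transcripts from a NuGENv2 or a TruSeq library, at 20M, 40M or 80M source reads (M, 1e6 reads). Each sample had 5 replicates. Reads in bins averaged 448593 ± 87716.5 (SD, n = 5) in the 1000 ng background and 347621 ± 78950.4 (SD, n = 5) in the 100 ng background with 20M NuGENv2 reads. With 80M TruSeq reads they averaged 483034 and 422744. The 100 ng sample with 20M TruSeq reads stood apart at 1212161, and every comparison with the TruSeq table at 20M reads carries that difference.

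Of the models with kit reads listed for 1 background only, the 3 with the largest change toward the 100 ng background at 80M TruSeq reads were Sirpa, Mgl2 and Pla2g15, all on its list. Mgl2 encodes a galactose-binding C-type lectin of macrophages and lies on chromosome 11 from 69943831 to 69951052 (NCBIM37). It measured 549 ± 49.9 FPKM equivalents in the 1000 ng background and 1919 ± 394 in the 100 ng background (SD, n = 5), a log2 fold change of -1.78 (SE 0.15, limma adjusted p = 8.11e-06). Sirpa, an inhibitory receptor that binds CD47, is on chromosome 2 from 129418571 to 129457964 and measured 72.2 ± 5.89 against 255 ± 52.4. Pla2g15, a lysosomal phospholipase, is on chromosome 8 from 108674299 to 108688613 and measured 7.30 ± 0.95 against 27.7 ± 5.74. The same kit reads were added to all 5 replicates, so after scaling their part runs inversely to the size factor. In the 100 ng background Mgl2 measured 2249 in replicate 2, with a size factor of 0.68, and 1454 in replicate 3, with 1.43. SDs and limma p-values of kit-read models thus partly reflect scaling and do not measure variation in the added reads. Toward the 1000 ng background, Aes, a corepressor of the Groucho family on chromosome 10 from 81022239 to 81029107, measured 500 ± 45.0 against 221 ± 28.8, a log2 fold change of 1.18 (SE 0.10, limma adjusted p = 8.47e-06). Gmfg and Saal1 followed among these models with log2 fold changes of 0.50 and 0.48. Gmfg passed the threshold narrowly, at a limma adjusted p of 0.045, and lost the call for most choices of a replicate left out, and under the exact permutation (adjusted p = 0.0575).

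**Figure D1:**
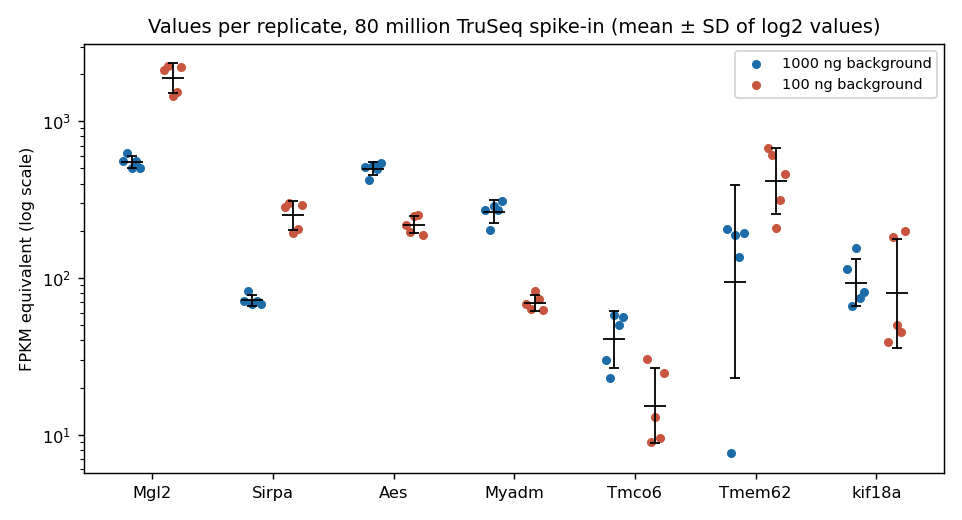
FPKM equivalents (log scale) of 7 gene models in the 5 replicates of each background with the TruSeq spike-in from 80M reads. Bars mark the mean and SD of the log2 values. Mgl2 averaged 1919 in the 100 ng background against 549 in the other, while the replicates of Tmem62 spread widely within each background.

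The first comparison asked which exon bins differ between the backgrounds at each kit and depth. With NuGENv2 reads, limma called 18 of 922 bins at 20M source reads, 46 at 40M and 113 at 80M. With TruSeq reads it called 156 bins at 40M and 197 at 80M, and 575 at 20M, where the 100 ng sample stood apart. Of the 197 bins, 73 were higher in the 1000 ng background and 124 in the 100 ng background. With size factors from the models of the kit-read lists alone, the split was 112 to 118. At 20M TruSeq reads the split moved from 301 against 274 to 226 against 545 after median-centring and to 353 against 54 with those size factors, so it has no stable direction. The 4 calls from the values as deposited, against 197, mix the lack of scaling with the other unit of the fifth 100 ng column. Without that column the values as deposited gave 118 calls. An exact permutation per bin has a smallest p of 0.00794 with 5 against 5 columns, so about 147 bins must reach it before any is called. It called 169 bins at 80M TruSeq reads, and 0 in the NuGENv2 tables and at 40M TruSeq reads, where limma's unadjusted p was under 0.05 for 164, 189, 229 and 262 bins. Those 0 counts reflect this floor and say little about the stability of calls.

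Counts of recovered transcripts were higher for kit reads than for either synthetic list in every table, a difference that was not tested and that counts transcripts of the same model separately. At 20M NuGENv2 reads they were 8 of 25, 4 of 25 and 4 of 27. At 80M TruSeq reads the models of 24 of 25 kit-read transcripts had a bin past the threshold in the listed direction, against 9 of 25 in the complex synthetic list and 6 of 27 in the endogenous one. Adjusted over the list alone these were 24, 4 and 6. Models of the synthetic lists gained no reads between tables, except in the TruSeq table at 20M reads. Among the other tables their calls therefore change only through scaling and steps shared over all bins. From 20M NuGENv2 to 80M TruSeq reads the complex list went from 4 to 9 and the endogenous one from 4 to 6. Adjusted over the list alone they stayed at 4 and 6, so these rises are not effects of depth or kit on synthetic reads. Of all 77 transcripts with a direction, 16, 24 and 36 were recovered with NuGENv2 reads at 20M, 40M and 80M, and 38 and 39 with TruSeq reads at 40M and 80M. Leaving out 1 replicate gave 4 to 15, 15 to 24 and 28 to 33 with NuGENv2 reads. Among the 44 transcripts whose model is listed for 1 background only, 27 were called in the listed direction and 3 in the opposite one at 80M TruSeq reads. At 20M TruSeq reads the totals were 57 recovered, with 35 of the 44 in the listed direction and 18 in the opposite one.

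Among synthetic models, Tmco6 rose in the 1000 ng background that lists it, at 43.5 ± 16.1 against 17.4 ± 9.74 (SD, n = 5), a log2 fold change of 1.35 (SE 0.40, limma adjusted p = 0.022), a call that an exact permutation did not keep (adjusted p = 0.0921). Hdh, which the naming rule did not take, also rose in the 1000 ng background that lists it. It measured 11.9 ± 2.09 against 8.93 ± 0.48, a log2 fold change of 0.36 (limma adjusted p = 0.022). With the same reads at 20M NuGENv2, the totals of Tmco6 and Hdh did not pass (limma adjusted p = 0.1124 and 0.1175). Both calls thus depend on scaling and adjustment. Dvl3, which transduces Wnt signals and is listed with different isoforms in both backgrounds, had 12 bins higher in the 1000 ng background and 1 in the other. Evi5l, likewise listed in both, had 6 bins higher in the 100 ng background. Both Dvl3 and Evi5l lost the call on model totals under several alternatives. Most other synthetic models did not pass on totals, and replicates of several differed widely. Tmem62 measured 146 ± 81.5 and 453 ± 195, with an adjusted p of 0.087 by limma. Its replicates did not overlap, at most 203.9 in the 1000 ng and at least 207.62 in the 100 ng background that lists it. Its exact permutation p, unadjusted, was therefore the smallest possible, 0.00794. Trm1l had 13 bins higher in the 100 ng background that lists it, although its total had an adjusted p of 0.43. Slc25a35, 2810002N01Rik, Bbs9, Sh3pxd2b, Casp9, kif18a, Rnf130, Tmem8, Thnsl1 and Atg16l1 did not pass on totals. The median SD of log2 model totals between replicates was 0.43 for synthetic models and 0.11 for kit-read models in the 1000 ng background at 80M TruSeq reads.

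Unlisted bins were seldom called. At 80M TruSeq reads, 1 of 65 tested bins of the 4 unlisted models passed, which was 0.51% of calls, and listed bins passed more often (Fisher's exact test, two-sided, p = 2.56e-06). That test counts bins as independent, although the 65 come from 4 models. It cannot show that calls are specific to listed transcripts, because unlisted models also had noisier replicates than kit-read models. At 80M TruSeq reads the median SD of log2 totals of unlisted models was 0.275 and 0.454, the background from more RNA first. It was 0.114 and 0.149 for kit-read models and 0.426 and 0.382 for synthetic ones. In both backgrounds 3 of the 4 unlisted models also exceeded 2 times the level of added reads described under Other observations. The unlisted bin called was the last of Parg, the enzyme that breaks down poly(ADP-ribose), at 17 ± 4.40 against 6.47 ± 2.65 (SD, n = 5). The model total of Parg did not pass, with a log2 fold change of 0.23 (limma adjusted p = 0.59). At 20M TruSeq reads 61 of 65 passed.

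Spike-in kit was compared over 17 models, of which 12 are listed for the 100 ng background and 5 for the other. The signed log2 fold change was larger with TruSeq than with NuGENv2 reads by 0.58 on average at 80M source reads, in 16 of 17 models (sign-flip permutation, two-sided, p = 0.00016, adjusted p = 0.00024). At 40M it was larger by 0.41, in 16 of 17 models (permutation p = 0.00011). At 20M it was larger by 0.09, in 13 of 17 models (permutation p = 0.069), a comparison that includes the sample that stood apart. The exception at 80M was Cyth4, with a signed change of 0.088 with NuGENv2 and -0.183 with TruSeq reads. The largest differences at 80M were in Pla2g15 at 1.27, Sirpa at 1.17 and Mgl2 at 1.02. Counted directly, from 40M to 80M source reads Mgl2 gained 23585 TruSeq and 6477 NuGENv2 reads, and Sirpa gained 7859 and 1849. Fxyd5, which regulates the sodium pump, is listed for both backgrounds and is not among the 17 models. Its gain went the other way, with 4179 TruSeq and 8070 NuGENv2 reads in the 1000 ng background. Over the listed models with a gain, which leaves out Myadm in the 100 ng background, the gain was 2.65 times larger with TruSeq in the 100 ng background (15 models, sign-flip permutation, exact, p = 0.0022) and 1.49 times in the 1000 ng background (9 models, exact p = 0.105), where a difference was not shown. The kits also differ in RNA input, 100 ng against 2 ng, so kit and input are not separable here.

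**Figure D2:**
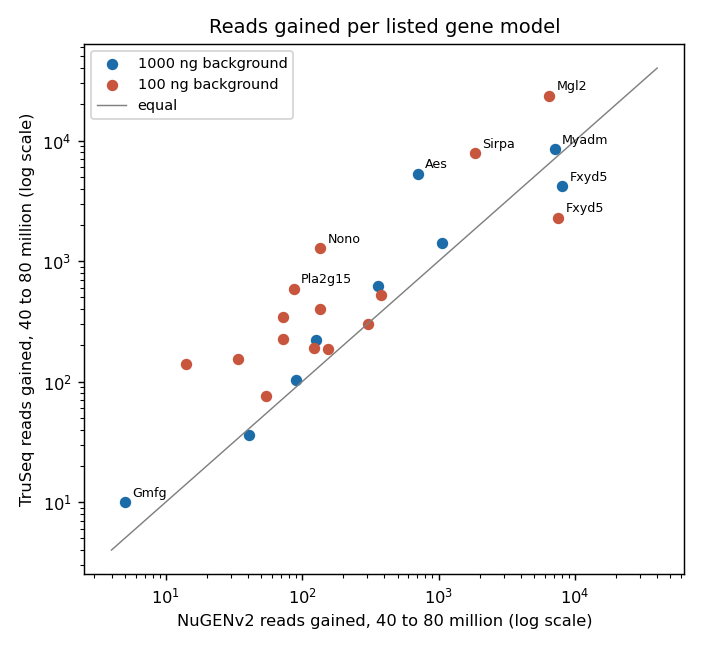
Reads gained by each listed gene model between 40M and 80M source reads, NuGENv2 on the horizontal and TruSeq on the vertical axis (both log scale), by background. Mgl2 gained 23585 TruSeq and 6477 NuGENv2 reads, above the line of equal gains, and both points of Fxyd5 lie under it.

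Deeper spike-ins raised the signed change within each kit. No bin fell with depth in the NuGENv2 tables, or from 40M to 80M in the TruSeq tables, so the direction there largely follows from the construction and only the size is a result. From 20M to 80M source reads the mean rise over 17 models was 0.25 with NuGENv2. From 40M to 80M it was 0.17 with NuGENv2 and 0.34 with TruSeq. The model that did not rise with TruSeq was Cyth4, a cytohesin that activates ARF proteins. It is listed for the 1000 ng background, yet measured 78.4 ± 1.26 there and 89.2 ± 2.50 in the 100 ng background (SD, n = 5), a log2 fold change of -0.18 that reversed to 0.23 under quantile normalization. TruSeq rises from 20M reads, 0.74 to 80M and 0.40 to 40M, include the sample that stood apart, and both turned negative on the values as deposited.

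**Figure D3:**
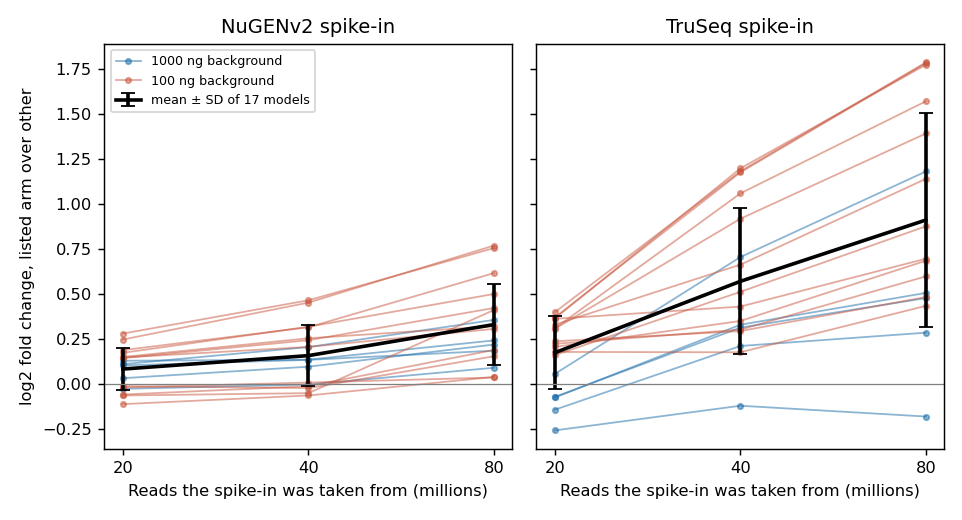
Signed log2 fold change of 17 kit-read gene models against the number of source reads, for NuGENv2 and TruSeq spike-ins, with the mean and SD over models in black. With TruSeq the mean rose by 0.34 from 40M to 80M reads, against 0.17 with NuGENv2.

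Lists were then compared with one another. At 80M TruSeq reads the mean signed change was 0.91 ± 0.59 over 17 kit-read models, 0.17 ± 0.45 over 12 complex synthetic models and 0.66 ± 0.71 over 9 endogenous synthetic models (SD over models). Kit-read and complex models differed by 0.74 (permutation test, two-sided, p = 0.0014, adjusted p = 0.012 over 18 comparisons), but by -0.01 on the values as deposited. Kit-read and endogenous models differed by 0.25 (permutation p = 0.35). At 20M NuGENv2 reads the kit-read models lay below the endogenous ones by 0.60 (permutation p = 0.00015, adjusted p = 0.0027). Synthetic models gained no reads between these tables, so the change between them follows from kit reads and scaling.

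Among the named models, bins of the same gene changed in opposite directions in Fxyd5, Ppp2r3a, Dvl3 and Cyth4. The bins named here were chosen after their values were seen. Cyth4, listed for the 1000 ng background only, had 1 bin higher there and 4 higher in the 100 ng background. No bin was assigned to a single isoform. Fxyd5 is listed in both backgrounds with different isoforms. Its bin E004, a coding part on chromosome 7 from 31820228 to 31820302, measured 2057 ± 190 in the 1000 ng and 886 ± 75.3 in the 100 ng background, while E012 measured 64.0 ± 4.81 against 131 ± 20.7 (SD, n = 5). Ppp2r3a and Elp2 are listed in both as well. Bins E001 and E016 of Ppp2r3a were higher in the 100 ng background, E002 and E003 in the other. For Elp2, a subunit of Elongator, 3 bins were higher in the 1000 ng background and none in the 100 ng background. Atg16l1, an autophagy gene of the complex list in both backgrounds, had 1 bin, E012, at 62.7 ± 40.5 against 4.49 ± 3.65. In 12 models, bins that gained reads with depth had a mean signed change of 0.87 at 80M TruSeq reads and bins that gained none had -0.02. That difference is built in, because the bins were chosen by their gain. Differential bin usage (limma diffSplice) was called in 20 of 21 kit-read models and 8 of 33 synthetic models at 80M TruSeq reads.

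Myadm, whose transcript uc009eup.1 is listed for both backgrounds, measured 268 ± 40.7 in the 1000 ng and 69.8 ± 8.12 in the 100 ng background (SD, n = 5), a log2 fold change of 1.92 (SE 0.13, limma adjusted p = 3.77e-06). Its 6 bins were all higher in the 1000 ng background. It gained 8467 TruSeq reads from 40M to 80M there and 0 in the 100 ng background.

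Samples with 1 background shared its reads. Between the 20M NuGENv2 and 80M TruSeq tables, 814 of 925 bins were identical in the 1000 ng background and 733 in the 100 ng background. For all 925 bins the difference between these tables was the same in each of the 5 replicates. The 100 ng sample with 20M TruSeq reads shared only 8 bins with the 20M NuGENv2 sample, and 916 bins were higher in it.

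**Figure D4:**
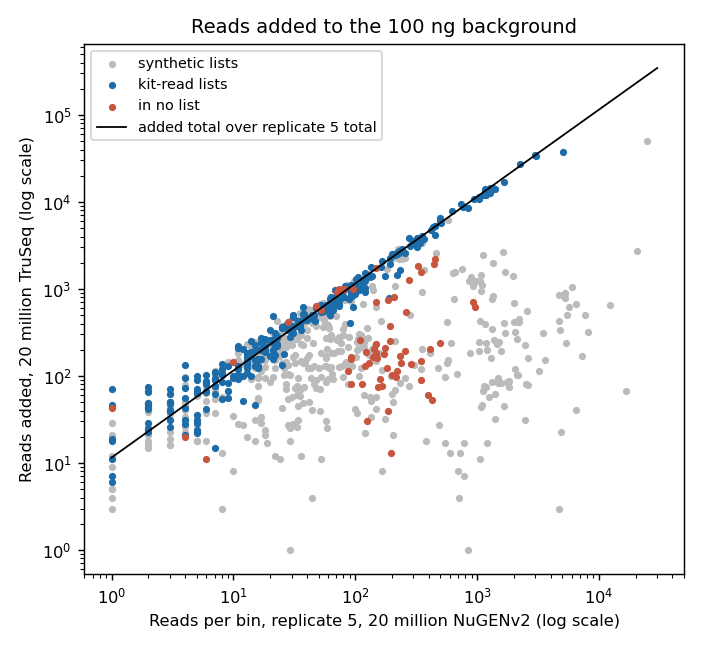
Reads added per bin in the 100 ng sample with 20M TruSeq reads, relative to the 20M NuGENv2 sample, against reads of replicate 5 in the latter (both log scale). Bins of kit-read models follow the line, which is the rise in the replicate 5 library total between the samples (184.9M) over its lower value (16M), 11.54.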

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

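The tests in this part were chosen after the results were seen, except the kit comparisons, which were planned.

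In the 100 ng sample with 20M TruSeq reads, 65 of 66 bins of models in no list gained reads, a signal outside the planned comparisons. In all, 864540 reads were added in 916 of 925 bins. More reads of the listed transcripts only is argued against by these unlisted bins, of which 98.5% gained reads. A candidate explanation is that a whole library was added. The reads added were a median of 11.26 times those of replicate 5 over 193 bins of kit-read models, and the library total of replicate 5 gives 11.54 (a rise of 184.9M, from 16M to 200.9M, over 16M). No biological explanation was tested, and why a whole library would have been added stays open.

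Cyth4 gained 1871 TruSeq reads from 40M to 80M in the 100 ng background, whose list does not name it. That the Cyth4 reads of the 1000 ng list were added to both backgrounds is argued against by 7 bins that gained reads in the 1000 ng background alone. Another 5 bins gained exactly as many reads in both backgrounds, so reads shared for part of the gene stay open. A candidate explanation is that the list of the 100 ng background names a Myadm transcript in place of a Cyth4 transcript, since Myadm gained 0 reads there. The labels alone cannot settle this, and no biological explanation was tested.

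Few bins were called from the values as deposited, 4 at 80M TruSeq reads. Leaving out the fifth 100 ng column, the one in another unit, gave 118, against 197 in the main result, so its unit may account for part of the loss there. It gave 55 against 4 at 40M and 760 against 2 at 20M TruSeq reads, and 54 against 8 at 80M NuGENv2 reads. At 20M and 40M NuGENv2 reads it gave 4 and 4 against 4 and 8, which decides nothing, because a replicate is lost too and the main counts were only 18 and 46. The deposited values also lack scaling by library size, and no biological explanation was tested.

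The signed log2 fold change differed between kits at matched depth by a sign-flip test, by 0.413 at 40M and 0.581 at 80M reads. A sample stood far from the other 4 in 1 of the 66 groups of 5 examined, fewer than the share of about 1 in 20 that chance gives. Sirpa in the 1000 ng background measured 82.4 in replicate 2 against a median of 70.9 (gap over range 0.748).

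Other splits of the 10 columns were fitted, 100 of 126 per table. In each table only 1 split, the real one, gave as many calls. The highest of the others was 0 in 5 tables, where the real split gave 18, 46, 113, 156 and 197, and 10 against 575 at 20M TruSeq reads. This says little about chance assignment of columns. The same kit reads were added to all 5 columns of a background, which by construction favours the real split. The tables also share their columns.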

How the results depend on the processing

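Calls were made from 5 columns against 5 with no statement of separate cultures, and bins with few reads limit what can be called. The planned values as deposited were replaced by scaled ones after the units were seen and before any fit was run, and this choice moves the results strongly. Alternatives added after seeing the data were size factors from kit-read models, filters on all bins, and gained bins in place of totals. The values as deposited, with and without the fifth 100 ng column, are grouped with them below. The values as deposited were nevertheless the planned scale. Mgl2, Sirpa, Pla2g15, Aes, Saal1, Myadm and Ppp2r3a kept their direction under every alternative fitted with limma on model totals. Their limma adjusted p stayed on the same side of the threshold. With the minimum absolute log2 fold change of 1, however, Saal1 at 0.48 and Ppp2r3a at -0.91 would not be called. These statements do not cover the values as deposited, on which limma was not run for totals. Signed changes of totals on those values entered only the comparisons of kits, depths and lists. The 4 bins called there at TruSeq 80M were all higher in the 1000 ng background, so bin calls toward the 100 ng background were lost. Of the values of counts and comparisons under the alternatives listed before the data were seen, leaving out replicates included, 685 stayed on their side, 67 counts moved by over 1.5 times, 19 results became stronger, 16 weaker and 4 reversed. Under the other group, which holds the planned values as deposited, these were 117, 31, 2, 3 and 12. The smaller number of reversals in the first group thus leaves out the planned scale. The cause of the changes below was not tested, except where fewer samples or a stricter threshold enter by construction. Counts are given in the order NuGENv2 20M, 40M and 80M, then TruSeq 20M, 40M and 80M, where the main counts were 18, 46, 113, 575, 156 and 197 bins called and 16, 24, 36, 57, 38 and 39 transcripts recovered.

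With an absolute log2 fold change of at least 1, bins called were 4, 13, 40, 229, 60 and 108, and recovered transcripts 5, 10 and 23 with NuGENv2, and 23 and 24 with TruSeq 20M and 40M. An exact permutation per bin called 0 bins, with 0 transcripts recovered and 0 unlisted bins, in the NuGENv2 tables and TruSeq 40M, where limma's unadjusted p was under 0.05 for 164, 189, 229 and 262 bins. These follow from the smallest exact p of 0.00794, which about 147 of the 922 bins must reach before any is called. With a filter of 5 on all bins, NuGENv2 20M and 40M gave 11 and 29 bins, and 20M recovered 10. At NuGENv2 20M, quantile normalization and kit-read size factors each called 7 bins and recovered 6 transcripts. Unlisted bins rose from 1 to 2 with quantile normalization at TruSeq 40M and 80M and with kit-read size factors at 80M.

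The values as deposited called 4, 8, 8, 2, 4 and 4 bins and recovered 2, 7, 7, 1, 2 and 2 transcripts, with 1 unlisted bin at NuGENv2 20M and 0 at TruSeq 20M (limma). Without the fifth 100 ng column they called 4, 4 and 54 bins with NuGENv2 and 55 and 118 with TruSeq 40M and 80M. They then recovered 5, 5 and 21 with NuGENv2 and 21 with TruSeq 40M, and called 0 unlisted bins at NuGENv2 40M and 35 at TruSeq 20M. On the values as deposited, TruSeq depth gave -0.07 for 80M against 20M and -0.438 for 40M against 20M. Kit-read minus complex models gave -0.926, -0.84, -0.643, 0.142, -0.376 and -0.008. Kit-read minus endogenous models gave -0.707 and -0.622 at NuGENv2 20M and 40M. Complex minus endogenous models gave 0.218, 0.218 and 0.219 with NuGENv2, and 0.219 and 0.22 with TruSeq 40M and 80M. Gained minus other bins gave 0.1 at TruSeq 20M.

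After median-centring, TruSeq depth 40M against 20M was 0.168, and complex minus endogenous at NuGENv2 80M was -0.543. With a pseudocount of 0.1 the latter was -0.562, and gained minus other bins at TruSeq 20M was 0.101. Gained bins in place of totals gave a kit difference of 0.095 at 20M. Quantile normalization turned Casp9 to 0.11, Cyth4 to 0.226, Elp2 to -0.02, Thnsl1 to 0.197 and Tmem8 to 0.071.

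The share of calls higher in the 1000 ng background moved at NuGENv2 20M from 61.1% to 85.7% with quantile normalization and to 42.9% with kit-read size factors. At TruSeq 20M it moved from 52.3% to 29.3% after centring, 32.7% with quantile normalization and 86.7% with kit-read size factors. At TruSeq 80M it moved from 37.1% to 48.7% with kit-read size factors. On the values as deposited it was 100% at NuGENv2 20M and TruSeq 40M and 80M, 87.5% at NuGENv2 40M and 80M, and 0% at TruSeq 20M.

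Replicate numbers do not pair the samples: correlations of deviations within a number ran from -0.382 to 0.091, and each replicate's best partner had another number. With the number as a replicate block, 1, 8 and 60 bins were called with NuGENv2 and 101 with TruSeq 40M. NuGENv2 20M and 40M recovered 2 and 8 transcripts, and 0 unlisted bins were called at NuGENv2 40M (limma, unadjusted p under 0.05 for 189 bins without the block). Model totals of Cyth4, Dvl3 and Gmfg lost their call in this paired fit, and no other named model did.

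Leaving out each replicate in turn gave these lowest and highest values. Bins called were 5 to 24, 21 to 53, 71 to 100, 489 to 613, 119 to 144, 156 to 190. Transcripts recovered were 4 to 15, 15 to 24, 28 to 33, 53 to 62, 32 to 37, 37 to 41. Unlisted bins were 0 to 0, 0 to 1, 1 to 2, 60 to 62, 1 to 2, 1 to 2 (limma, unadjusted counts with all replicates 164 to 610). The kit difference was 0.077 to 0.098, 0.391 to 0.445, 0.556 to 0.619 at 20M, 40M and 80M. Depth rises 80M against 20M, 40M against 20M and 80M against 40M were 0.236 to 0.266, 0.07 to 0.081, 0.165 to 0.185 with NuGENv2 and 0.698 to 0.788, 0.368 to 0.428, 0.329 to 0.359 with TruSeq. Kit-read minus complex models gave -0.138 to -0.015, -0.064 to 0.056, 0.109 to 0.221, -0.61 to -0.48, 0.343 to 0.468, 0.675 to 0.819. Kit-read minus endogenous models gave -0.729 to -0.496, -0.652 to -0.416, -0.477 to -0.235, 0.002 to 0.235, -0.23 to 0.017, 0.113 to 0.37. Complex minus endogenous models gave -0.698 to -0.358, -0.691 to -0.352, -0.677 to -0.343, 0.508 to 0.844, -0.659 to -0.325, -0.643 to -0.316. Gained minus other bins gave 0.064 to 0.1, 0.132 to 0.169, 0.347 to 0.407, 0.074 to 0.102, 0.51 to 0.59, 0.835 to 0.944. Model totals at TruSeq 80M were 2810002N01Rik 0.939 to 1.609, Aes 1.125 to 1.236, Atg16l1 -0.067 to 0.457, Bbs9 0.308 to 0.737, Casp9 -0.508 to 0.351, Cyth4 -0.199 to -0.173, Dvl3 0.452 to 0.741, Elp2 0.023 to 0.073, Evi5l -0.755 to -0.543, Fxyd5 0.241 to 0.265. Further totals were Gmfg 0.362 to 0.628, kif18a -0.028 to 0.551, Mgl2 -1.875 to -1.717, Myadm 1.864 to 2.019, Parg -0.042 to 0.414, Pla2g15 -1.865 to -1.708, Ppp2r3a -0.983 to -0.86, Rnf130 -0.369 to 0.072. The last were Saal1 0.439 to 0.505, Sh3pxd2b -0.422 to -0.097, Sirpa -1.88 to -1.719, Slc25a35 -1.806 to -1.107, Thnsl1 -0.476 to -0.129, Tmco6 1.167 to 1.58, Tmem62 -2.359 to -1.215, Tmem8 -0.356 to -0.219, Trm1l -0.882 to -0.324. Rnf130 turned to 0.072, 0.012 and 0.05 without replicate 4 of the 1000 ng background or replicates 1 and 5 of the 100 ng background. Atg16l1, Casp9, Parg and kif18a turned to -0.067, 0.351, -0.042 and -0.028 without 1 replicate each. Bins called moved by over 1.5 times at NuGENv2 20M without replicates 1, 3, 4 or 5 of the 1000 ng background or 1, 2, 4 or 5 of the 100 ng background. At NuGENv2 40M this held for replicates 3 and 4 and for 1, 2 and 4, and at 80M for replicate 3 of the 1000 ng background.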

Other observations

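All tests in this part were chosen after the results were seen. The reads added to the 100 ng sample at 20M TruSeq reads were taken as a level of each gene to compare with. That they are a whole library (11.26 times replicate 5 per bin, against 11.54 from the rise in its library total) is only a candidate explanation, and whether they hold synthetic reads was not tested. The models named here were chosen after their values were seen. On this scale 2810002N01Rik stood at 223 times that level in the 1000 ng background, Tmem62 at 149 times in the 100 ng background, and kif18a, a mitotic kinesin, at 76.1 and 69.0 times. Synthetic models were raised in the background that does not list them too. Casp9, the initiator caspase, was at 35.3 times where listed and 44.8 times where not. Of 13 models of the complex list in the 1000 ng background 10 exceeded 2 times, and of 11 synthetic models listed only for the other background 4 did. In the 100 ng background these were 5 of 10 and 7 of 11, and 8 of 13 for the endogenous list, which in the 1000 ng background had 6 of 9. Over 10 times, the 100 ng background had 3 of 10 complex, 5 of 13 endogenous and 1 of 11 other models, and the 1000 ng background 5 of 13, 2 of 9 and 2 of 11. No test of these differences was run.

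Several models with a listed synthetic transcript stood at the level of the added reads. Tgfbrap1 was at 0.99 times in both backgrounds, Pla2g16 at 0.92 and 0.96, Cbx7 at 0.90 where listed, and Arpp19 at 1.05. Of the unlisted models, Parg, Phospho2 and Sin3b stood at 8.63, 10.39 and 3.43 times in the 1000 ng background, and Tom40, a channel of mitochondrial import, at 0.93.

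The hypothesis that NuGENv2 reads are spread less evenly over a model than TruSeq reads was tested by the share of gained reads in the largest bin. This share was lower with NuGENv2, 42.8% against 51.5%, a mean difference of -8.7 percentage points (SD 14.5) over 22 combinations of model and background. Counting each of 19 models once it was -7.3 (SD 13.2), with 6 higher for NuGENv2 (sign-flip permutation, two-sided, p = 0.0245), and -5.3 without Fxyd5, which differed most (permutation p = 0.0465). The larger share with NuGENv2 that the hypothesis predicted was not found. The opposite difference was narrow once Fxyd5 is left out. Bin lengths differ within models, so the share is not a measure of coverage along the transcript and cannot decide the hypothesis. Kit and RNA input are not separable here either.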
